A study of Homo sapiens with 4 samples.

How the data were processed

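Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody to the transcription factor SOX2 was done in 2 human cell lines. CWR-R1 is a prostate carcinoma line derived from a CWR22 xenograft that had relapsed after castration. WA01 is a pluripotent human embryonic stem cell line. By title, each line had 1 IP library and 1 input library, so there were 4 groups of 1 library and 4 libraries in all. Per the labels, cells were fixed for 15 min, chromatin was sheared in 5 cycles of 30 s to about 200 bp, libraries were made from 5 ng of DNA with 13 PCR cycles, and reads were 50 bp long. PCR duplicates are not independent molecules, and the interval of a gene value covers counting error only. Intervals of coverage steps and of slopes instead show spread over genes or over chromosomes. None of them covers the spread between replicates.

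Each deposited table held 1 library with 20076 protein-coding genes, and per the file headers it gave an expected count, a TPM and an FPKM for each gene. The expected counts, deposited unscaled, were estimated reads over the transcripts of a gene, so binding in introns or between genes was not seen in them. The deposited TPM values (transcript abundance scaled by length and library) served for the coverage of each library on its own. The deposited FPKM values (fragments scaled by length and library) were proportional to TPM within a library and were not used in any computation. In the submitters' processing notes the authors named CASAVA 1.8, Trimmomatic 0.38, Bowtie2, SAMtools, Picard 2.18.10, MACS2, HOMER 4.9.1 and the builds hg38 and GRCh38.p12. The program that gave the expected counts is not stated in the sources used here, nor is whether the gene tables pool replicates. Peak lists were not analysed here.

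Of the genes, 25.6% had an expected count further than 0.005 from a whole number in at least 1 library, which marks reads shared out between genes. The other 14927 genes are called counted whole. In the tables, 28 symbols had been turned into dates and 50 entries carried a repeated symbol; genes were therefore joined by gene identifier.

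Counts were rounded and scaled to the total count of the library. The value of a gene was the log2 ratio of IP over input after adding 0.5 counts to each library. Its 95% interval came from the exact Clopper-Pearson interval of the share of counts in the IP. A gene was called higher in the IP when the ratio was at least 2-fold, the interval excluded equality and the pair of libraries held at least 20 counts, and lower by the mirror of that rule. The difference between lines was the CWR-R1 log2 ratio minus the WA01 log2 ratio, with a delta-method interval from the 4 counts; a gene was called at a difference of at least 1 with an interval that excluded 0. No test across genes was run and no p-value was computed. A fit of IP against input with line as block would leave 1 residual degree of freedom and take the lines as replicates; it was not run. The difference between lines leaves 0 residual degrees of freedom and could not be set against a spread between replicates. Where a gene had a count of 0 in 1 library, the fold is given as a bound against a floor of 3 counts in that library.

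Genes were named by a rule fixed before the data were examined: SOX2, the 10 highest and 5 lowest called genes of each comparison with at least 50 counts in each pair of libraries compared, and the 2 highest and 2 lowest members of each gene list. Y-linked genes were not named, and the values of some genes that the rule names are not reported here. Because the highest values were mostly in genes with shared reads, the same rule was applied again to genes counted whole, a choice made after the values were seen; the genes named for IP over IP and for opposite directions were also chosen then. The 17 gene lists, fixed before the data were examined, were pluripotency, neural and neuroendocrine, SOX family, germ layer differentiation, prostate luminal and androgen response, basal epithelial, fibroblast, glycolysis, TCA cycle, oxidative phosphorylation, serine and one-carbon, lipid synthesis and oxidation, cell cycle, HOX clusters, ribosomal proteins, liver and muscle genes, and olfactory receptors. Of the listed symbols 11 were matched through an older symbol, 9 of them in oxidative phosphorylation. The median of each list was placed among 10000 random lists of the same size matched on mean count in 20 bins, and a list was called outside when it fell below the lowest 2.5% or above the highest 2.5% of them. With 17 lists, 0.85 lists per comparison would fall outside by chance; 51 list comparisons were made, and 51 more, of the inputs and of IP over IP, were added after the data were seen. Random lists drew single genes from anywhere in the genome. For lists of clustered genes, such as HOX clusters and olfactory receptors, the random range may be too narrow. The lists also overlap, with SOX1 and SOX21 on the SOX family and neural lists and SOX17 on the SOX family and germ layer lists.

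The inputs of the lines were compared per gene, per chromosome and in 236 windows of about 60 genes. The coverage of each library alone was the log2 of TPM with 0.1 added, adjusted for gene density in 10 classes, over 13960 genes with at least 50 counts in the 4 libraries together. Steps over chromosome segments were medians against the chromosomes outside the segments, with 95% intervals from 1000 bootstrap resamples of genes. The resampling takes neighbouring genes as independent, which genes of 1 segment need not be. The interval of a mixed share carries only the bootstrap of the library labelled WA01 IP, with the step of the reference library held fixed. The segments were chosen from the ratio of the inputs, and this coverage comparison was added after the data were seen. Gene density was the number of listed genes within 1 Mb.

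The rule was tested on simulated data. Of 100 genes changed 3-fold up or down among 20076, the rule called 99 and 98 in simulated CWR-R1 libraries, and 100 and 86 in simulated WA01 libraries, where the IP was shallower. Of 100 genes given a 4-fold difference between lines it called 99 up and 97 down. Between 18 and 139 other genes were called in these runs. Simulated IP counts were Poisson draws around the input titled for the same line, without duplicates, added spread or a gene density trend. These numbers are therefore not a rate of false calls in the real libraries. For the coverage steps, the largest error over 12 simulated steps was 0.07 on the log2 scale.

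Alternatives fixed before the data were examined were TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), totals over autosomal genes, no count minimum or a minimum of 100, 5 counts added, size rules of 1.5-fold and 3-fold, the input of the other line, and for the lists matching on gene length and means in place of medians. Chosen after the data were seen were genes counted whole, the CWR-R1 input for both IPs, the leaving out of chromosomes 1, 2, 7, 8, 11 and 12, and lists matched on gene density. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

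The labels conflict in places. The cell line field of the CWR-R1 input names CWR-22Rv1, a related line. Both inputs list a goat IgG as antibody although their titles call them input. The extraction text describes an immunoprecipitation of MEIS1, and the WA01 libraries carry the growth text of CWR-R1. Both IPs carry a label of exogenous SOX2 expression that the inputs lack. No genome sequence was used, so GC content was not examined.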

Results

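SOX2-bound DNA was sequenced in CWR-R1 prostate carcinoma cells and in a library labelled WA01, a human embryonic stem cell line, each beside an input library titled for the same line. The cell line field of the CWR-R1 input names CWR-22Rv1, a related line. Each of the 4 groups held 1 library, so no value could be checked against replicates, and the intervals of gene values cover counting error only. Total counts over genes were 2848122 in the CWR-R1 IP, 4744368 in the CWR-R1 input, 989465 in the library labelled WA01 IP and 3045515 in the WA01 input. The median count per gene was 100, 165, 35 and 110 in the same order. A count of 0 allowed up to 1.05, 0.632, 3.03 and 0.985 CPM (counts scaled to the library total). The counts covered transcribed parts of genes only; positions are those of the deposited tables, whose processing notes name build GRCh38.p12.

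Long chromosome segments of CWR-R1 stood apart from WA01 in the inputs, and the same segments stood apart in the library labelled WA01 IP. The question was whether inputs differ between the lines in ways that ratios would carry. Window ratios of CWR-R1 input over WA01 input were averaged per segment and set against the mean of the other chromosomes. On the log2 scale these means were 0.45 higher over chromosomes 7, 8 and 12, and 0.43 higher over distal 1q. Over 2q from 118.8 to 178.8 Mb the value was -0.78. With coverage of each library taken alone, the 2q step was -0.88 (95% interval -1.03 to -0.80) in the CWR-R1 input and -0.80 (-0.91 to -0.71) in the CWR-R1 IP. In the WA01 input the 2q step was 0.02 (-0.05 to 0.14), and in the library labelled WA01 IP it was -0.60 (-0.78 to -0.35). Over chromosomes 7, 8 and 12 the steps were 0.47, 0.46 and 0.01 in those first 3 libraries and 0.39 (0.32 to 0.43) in the library labelled WA01 IP. Single windows of that library outside the segments also lay low, at -1.014 on chromosome 11 (3638506 to 6272127) and -0.874 on chromosome 6 (30914208 to 33080778). Its windows in the lost part of 2q lay at -0.407, -0.853 and -0.346. The bootstrap over genes does not show this spread between windows. In the same library the steps over distal 1q, 0.14 (0.06 to 0.20), and distal 11q, 0.09 (0.02 to 0.24), were smaller than the 0.47 and 0.30 of the CWR-R1 input. The CWR-R1 IP lay between, at 0.323 (0.256 to 0.365) over 1q and 0.220 (0.151 to 0.286) over 11q. Its 11q interval overlapped that of the library labelled WA01 IP. Its 1q interval did not overlap that of the CWR-R1 input, 0.432 to 0.525, while the intervals of these libraries overlapped over the other segments. The steps thus do not settle whether the CWR-R1 input, whose cell line field names CWR-22Rv1, is of the same line as the CWR-R1 IP. All values of the library labelled WA01 IP below are given under its label.

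**Figure D1:**
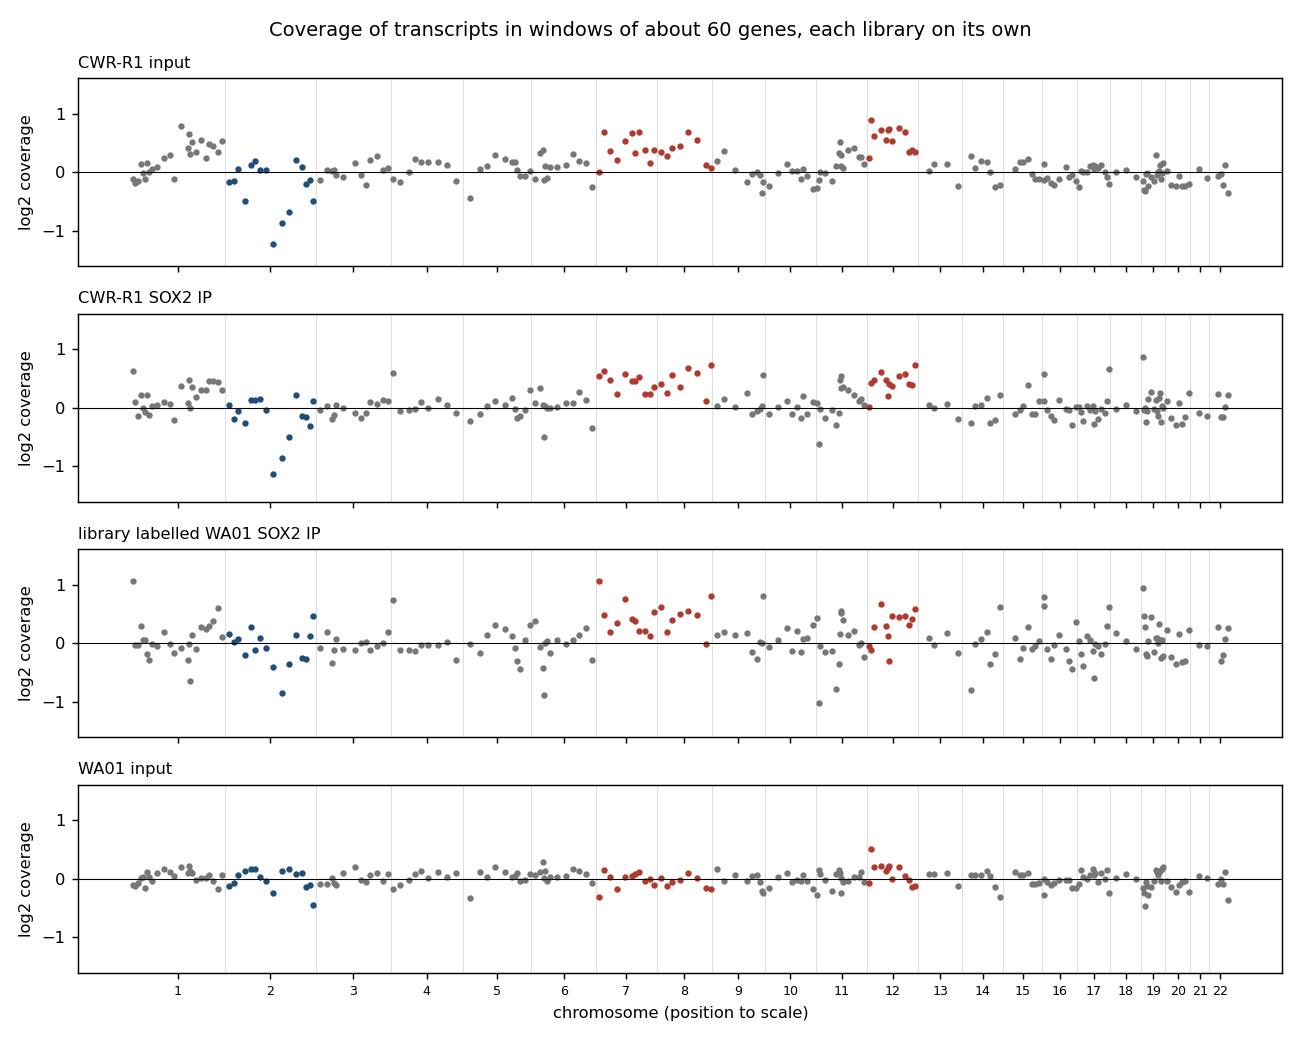
Coverage of each of the 4 libraries on its own along the genome: each point is a window of about 60 genes, the x axis is genome position by chromosome, and the y axis is the log2 coverage after removing the gene density trend, with chromosome 2 in blue and chromosomes 7, 8 and 12 in red. Over the lost part of 2q the step was -0.60 in the library labelled WA01 IP, against -0.88 in the CWR-R1 input and 0.02 in the WA01 input.

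Pluripotency genes were low and prostate genes high in CWR-R1 input over WA01 input. Of 35 pluripotency genes 22 had an interval below 0 and 3 above it, and of 26 prostate genes 14 had an interval above 0 and 2 below it. The pluripotency genes had a median of -0.50, below all 10000 random lists, with RIF1 at -1.06 (-1.25 to -0.88), SALL4 at -0.73 (-0.93 to -0.52), POU5F1, the pluripotency factor OCT4, at -0.64 (-0.93 to -0.35) and NANOG at -0.42 (-0.66 to -0.18). Prostate luminal and androgen response genes had a median of 0.35, at percentile 100, with FOLH1, which encodes the prostate surface antigen PSMA, at 0.87 (0.45 to 1.30), STEAP2 at 0.74 (0.57 to 0.91) and KLK3, which encodes prostate-specific antigen, at 0.66 (0.17 to 1.14). RIF1 lies in the lost part of 2q, and STEAP2 lies on chromosome 7. After the window ratio was subtracted the list medians were -0.44 and 0.13, the latter within the random range at percentile 97.3. Other lists also lay outside in the ratio of the inputs. SOX family (median -0.38, percentile 0.01), neural (-0.23, 0.53) and germ layer genes (-0.30, 0.73) lay below, and stayed below after the window ratio was subtracted. TCA cycle (0.27, 99.97) and ribosomal protein genes (0.08, 98.6) lay above, and were then within the range at 97.4 and 95.9. After the subtraction HOX (2.26) and basal epithelial genes (2.35) lay below and cell cycle genes (99.1) above.

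SOX2 itself (gene10844, chromosome 3, 181711924 to 181714436) stood at 2.0-fold over input in CWR-R1 (1.63 to 2.45; log2 interval 0.71 to 1.30), which fell just short of the 2-fold rule before rounding. It was 1.19-fold (0.85 to 1.64; log2 0.26) in the library labelled WA01 IP. Its counts were 215 in the CWR-R1 IP, 179 in the CWR-R1 input, 54 in the library labelled WA01 IP and 140 in the WA01 input. The difference between the lines was 0.74 (0.21 to 1.28), below the size rule of 1. SOX2 has a single exon and is not counted whole, and the IPs carry a label of exogenous SOX2 that the inputs lack, so reads from an introduced copy are not separated from those of the chromosomal gene.

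The CWR-R1 IP over its input asks which genes carry SOX2 in the prostate cancer line. Among the 10 highest genes counted whole were the transcription factor genes ONECUT3, UNCX, SOX18 and BHLHA9. ONECUT3 (chromosome 19, 1753663 to 1775445), a homeobox gene, was 25.6-fold over input (18.8 to 36.6). NRARP (chromosome 9, 137299631 to 137302251), a feedback regulator of Notch signalling, was 22.3-fold over input (19.1 to 26.2) on 2358 IP counts. The homeobox gene UNCX was 17.8-fold (14.0 to 23.1), the IGF-binding protein gene IGFBP2 17.5-fold (13.4 to 23.8) and SOX18 17.2-fold (13.4 to 22.9). Others of the 10 highest were TMEM238 at 30.8-fold (20.5 to 50.8), BHLHA9 at 18.8-fold and SHISA8 at 17.3-fold. Among the lowest genes counted whole were the cancer-testis antigen gene MAGEA1, at a log2 of -3.63 (-7.02 to -2.01) on 2 IP counts, LRRC72 at -2.84 and ANKRD66 at -2.63. GIMAP5 had 0 counts in the IP against 103 in the input, at least 20.6-fold lower, and COMMD3-BMI1 was at least 11.2-fold lower; GIMAP5 overlaps a read-through gene and COMMD3-BMI1 is one.

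Without the restriction to genes counted whole, the highest values included members of families of near-identical genes. F8A2 and F8A3 each had 613 IP counts and 0 input counts, at least 340-fold higher, and TRIM49D1 was at least 50.5-fold higher. LRRC24, for which no such family was examined, was at least 104-fold higher. The lowest included TBC1D3L, at least 23.2-fold lower. The F8A, TRIM49 and TBC1D3 genes share reads with near-identical copies. The 3 F8A genes summed were 12.1-fold over input (10.4 to 14.2) and the TBC1D3 genes summed were at a log2 of -0.13.

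In all, 1595 genes were higher and 894 lower in the CWR-R1 IP, of 19650 with enough counts. The median of all genes was -0.16. Higher genes made up 64.1% of the called genes with total-count scaling, 76.1% with TMM factors and 77.9% with median-of-ratios factors, which moved all values by 0.13 and 0.15. With median-of-ratios factors the count of lower genes fell to 571, and among genes counted whole it was 585.

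**Figure D2:**
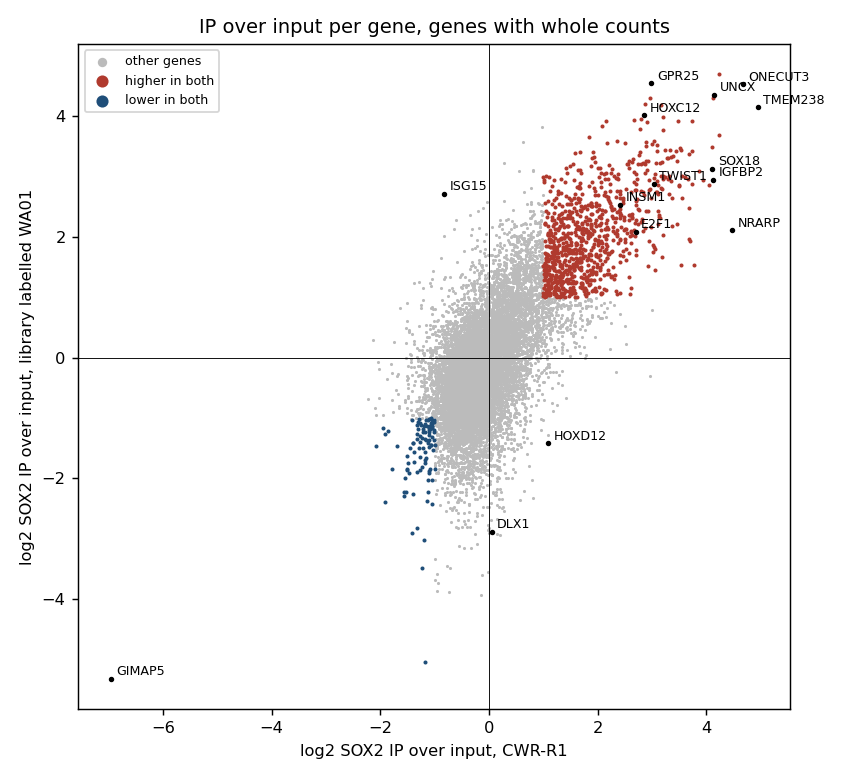
IP over input in CWR-R1 (x axis, log2) against IP over input in the libraries labelled WA01 (y axis, log2), for 12922 genes counted whole with at least 50 counts in each pair of libraries; each point is a gene, red marks genes higher in both and blue genes lower in both. Of these, 890 were higher in both and 100 lower in both.

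In the gene lists, SOX family, neural and HOX genes stood above genes of like depth in the CWR-R1 IP. Of 18 SOX family genes 8 were higher and 0 lower (median 0.75, percentile 99.98), with SOX18 and SOX3 at 4.11 and 3.25. Of 25 neural and neuroendocrine genes 9 were higher and 0 lower (median 0.44, percentile 99.97), among them the neuroendocrine transcription factor gene INSM1 at 2.41 (5.31-fold, 4.46 to 6.39) and LHX2 at 2.04. Of 38 HOX genes 9 were higher and 0 lower (median 0.39, percentile 100), with HOXC12 at 2.86 and HOXD11 at 2.16. Of 20 germ layer genes 5 were higher and 0 lower (median 0.22, percentile 98.1; 94.4, within the range, when matched on gene length), with FOXA2 3.04-fold and MESP1 2.93-fold over input. Of 35 pluripotency genes 5 were higher and 1 lower (median 0.00, percentile 90.3, within the random range), with UTF1 at 2.84 and TCF7L1 at 2.53 and the signal gene NODAL at -1.27. Fibroblast genes (median -0.48, percentile 0.67; within the range by the mean) and olfactory receptors (median -0.32, percentile 0.40; 5 higher and 61 lower of 369) lay below, although TWIST1 stood at 3.03. Olfactory receptors counted whole lay within the range (percentile 12.7), and with the WA01 input as denominator so did the neural (88.9), germ layer (61.4), fibroblast (7.27) and olfactory (5.24) lists, while prostate genes lay above it (97.9) and liver and muscle genes below (0.29).

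Metabolic genes, the subject of the series title, had few calls in CWR-R1. Of 25 glycolysis genes 0 were higher and 1 was lower (median -0.11, percentile 55.6). Of 25 TCA cycle genes only the mitochondrial isocitrate dehydrogenase gene IDH2 was higher, at 1.26 (2.40-fold, 1.68 to 3.47), and the list median was -0.31 (percentile 8.3). In oxidative phosphorylation COX4I1 was higher at 1.39 (2.63-fold, 1.51 to 4.74), and COX7C and NDUFS4 were lower at -1.59 and -1.12, of 41 genes (median -0.26, percentile 24.6). The thymidylate synthase gene TYMS was higher at 1.28, the 1 call among 23 serine and one-carbon genes (median -0.01, percentile 84.7). Of 28 lipid genes only ETFA was lower, at -1.12 (median -0.17, percentile 44.3). All 5 of these lists lay within the random range.

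With its own input the remaining lists also lay within it. Of 26 prostate genes PMEPA1, an androgen- and TGF-beta-responsive gene, was higher at 1.59 and ERG lower at -1.08 (median -0.36, percentile 3.23). Of 28 cell cycle genes E2F1, at 2.70, and CCNE1, at 2.14, were higher (median 0.01, percentile 88.7). None of 12 basal epithelial genes was called (median -0.14, percentile 46.1). Ribosomal protein genes had 4 higher and 5 lower of 36 (median -0.08, percentile 76.3), and liver and muscle genes 1 higher and 2 lower of 27 (median -0.35, percentile 8.5).

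The IP labelled WA01 over the WA01 input asks the same of the stem cell line. The highest genes counted whole again included ONECUT3, 23.1-fold over input (15.7 to 36.5), UNCX, 20.6-fold (15.0 to 29.3), and TMEM238, 17.7-fold (10.3 to 34.8). GPR25 (chromosome 1, 200872955 to 200874178), an orphan receptor gene, was 23.4-fold over input (14.8 to 41.0). The neuropeptide gene NPB was at 19.8-fold, METRN at 18.5-fold, GP1BB at 18.3-fold and the growth factor gene FGF22 at 16.3-fold. POU3F3, a neural POU-domain gene not counted whole, was at 21.1-fold. Among the lowest were TRIML1 at a log2 of -3.93 (-9.83 to -1.98) and PDILT at -3.89 (-9.79 to -1.94), each with 1 IP count, and IQCF3, with 0 IP counts, at least 5.42-fold lower.

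In this library 2529 genes were higher and 2916 lower of 19313, and the median of all genes was -0.24. Higher genes made up 46.4% of the called genes with total-count scaling but 64.0% with TMM factors and 65.4% with median-of-ratios factors, which moved all values by 0.22 and 0.24, so the side with more genes turned with the scaling. The lost part of 2q held 4.70% of the lower genes, 137 of 2916, against 1.24% of all tested genes. Chromosomes 7, 8 and 12 held 16.4% of the higher genes against 13.5% of those tested.

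The same gene groups stood above genes of like depth in the library labelled WA01 IP. Of 18 SOX family genes 7 were higher and 0 lower (median 0.72, percentile 99.99), with SOX18 8.76-fold (6.59 to 11.9) and SOX3 8.0-fold (5.32 to 12.6) over input. Neural genes had 8 higher and 1 lower (median 0.48, percentile 99.8; 95.6, within the range, among genes counted whole), with INSM1 at 2.53 and the forebrain gene ZIC2 at 2.03. HOX genes had 11 higher, with HOXC12 at 4.02 and HOXA4 at 3.24, and 2 lower, HOXD4 at -2.36 and HOXD12 at -1.42 (median 0.66, percentile 100). Both lower genes lie in the lost part of 2q, and with the CWR-R1 input HOXD12 stood at 0.99. Ribosomal protein genes had 9 higher and 4 lower of 33 (median 0.44, percentile 99.9; 22.9 with a count minimum of 100 and 90.2 when matched on gene length), with RPS15 at 2.40. Liver and muscle genes (median -0.80, percentile 0.54; 2 higher and 9 lower of 25, and within the range by the mean) and olfactory receptors (median -0.87, percentile 0.00; 10 higher and 124 lower of 354) lay below.

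Pluripotency genes went both ways in the library labelled WA01 IP, with 9 higher and 13 lower of 35 (median -0.30, percentile 29.2). FOXD3 at 2.54 and ZSCAN10 at 2.43 were higher, and OTX2 at -2.02 and DPPA4 at -1.82 were lower. At pluripotency genes the CWR-R1 input over WA01 input was low, with a median of -0.50, 22 of 35 intervals below 0 and 3 above. Their negative median and lower calls thus rest in part on the WA01 input. Metabolic genes also went both ways. Glycolysis had 4 higher and 4 lower, with GAPDH at 1.66 (3.16-fold, 2.27 to 4.41), PFKL at 1.33 and the glucose transporter gene SLC2A3 at -2.27 (median -0.03, percentile 76.5). The TCA cycle had 3 higher and 6 lower, with IDH2 at 2.13 and SDHB at -2.94 (-8.85 to -0.94) on 1 IP count (median -0.24, percentile 46.4). Oxidative phosphorylation had 6 higher and 4 lower of 40, with ATP5D at 3.09, CYC1 at 2.44 and COX6C at -3.17 (-9.07 to -1.18) on 1 IP count (median -0.02, percentile 93.0; above the range at 97.7 among genes counted whole). Lipid genes had 3 higher, among them the fatty acid synthase gene FASN at 1.72 and INSIG1 at 1.31, and 1 lower (median -0.04, percentile 83.1). INSIG1 lies on chromosome 7 and had a CWR-R1 input over WA01 input of 0.812 (0.502 to 1.123), so its call rests on the WA01 input. Serine and one-carbon genes had 2 higher, TYMS at 1.41 and SLC1A5 at 1.39, and 1 lower, GOT1 at -1.62 (median -0.05, percentile 78.2).

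Of the other lists, 8 of 20 germ layer genes were higher and 0 lower, with MESP1 at 3.21 and GATA6 at 2.24 (median 0.26, percentile 95.1). Prostate genes had 0 higher and 3 lower, with TMPRSS2 at -1.44 and ERG at -1.13, while their median was above 0 (0.16, percentile 96.1; above the range at 98.3 when matched on gene length). Cell cycle genes had 3 higher and 3 lower, with CCNE1 at 2.96 and E2F1 at 2.09 (median -0.13, percentile 68.9). Basal epithelial genes had 1 higher and 3 lower (median -0.24, percentile 44.4), and fibroblast genes 1 higher, TWIST1 at 2.88, and 4 lower (median -0.53, percentile 8.29).

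**Figure D3:**
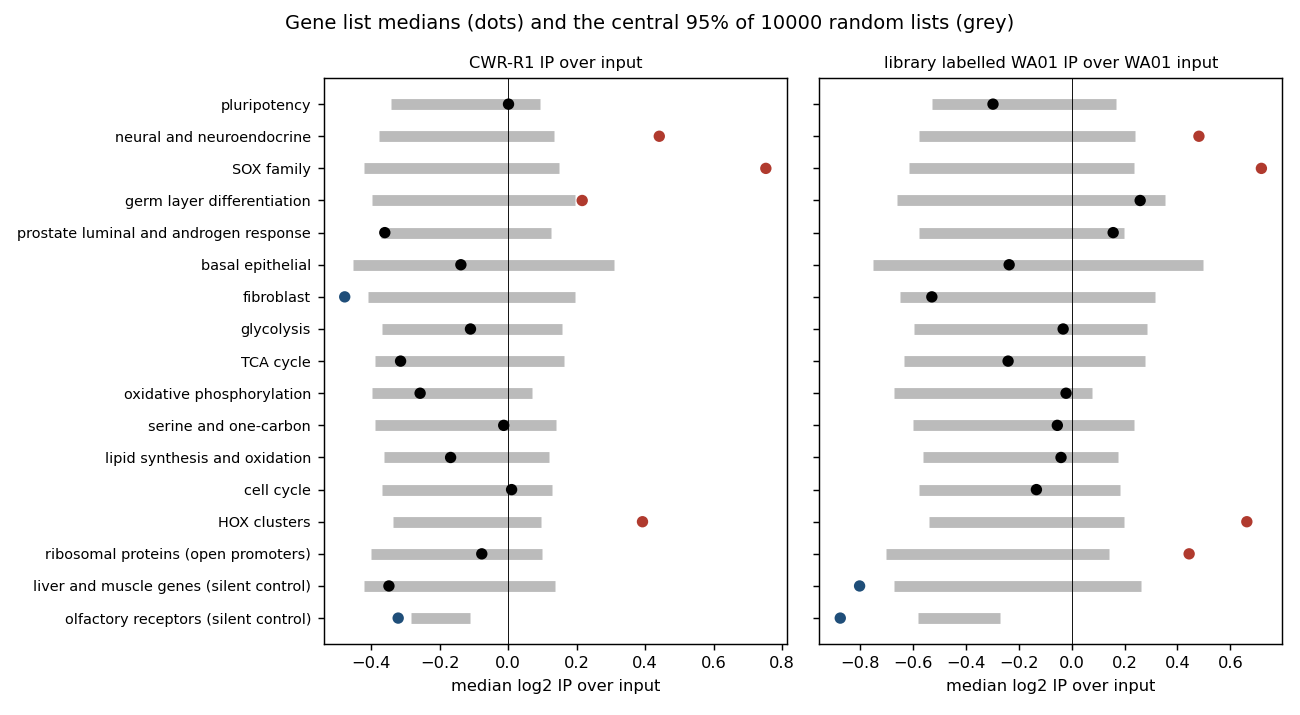
Median log2 IP over input of each of the 17 gene lists (dots, x axis) in CWR-R1 (left) and in the libraries labelled WA01 (right), each over a grey bar that holds the central 95% of 10000 random lists matched on mean count; red dots lie above it and blue dots below. SOX family, neural and HOX genes lay above the range in both IPs, at medians of 0.75, 0.44 and 0.39 in CWR-R1.

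Enrichment was shared between the IPs far beyond independent sets, in the comparison that asks whether the same genes carry SOX2 in both lines. Of 19261 genes tested in both, 1188 were higher in both IPs, against 204 for independent sets, and 261 were lower in both, against 125. Independent sets do not allow for trends that the IPs have in common, such as more higher calls in gene-dense regions. The excess is therefore not by itself shared SOX2 binding. ONECUT3, TMEM238, UNCX, SOX18, SOX3, INSM1, TWIST1, E2F1 and CCNE1 were higher in both, and ERG and NODAL were lower in both. ERG had a CWR-R1 input over WA01 input of -0.452, and against the CWR-R1 input its value in the library labelled WA01 IP falls short of the size rule. Across genes the ratios had a Pearson r of 0.60 and a Spearman rho of 0.52; genes are not independent replicates. With TMM factors 136 genes were lower in both, against 52.1 for independent sets. Because the library labelled WA01 IP stepped over the same segments as the CWR-R1 libraries, the overlap is between libraries and not shown to be between lines.

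Genes with larger IP over input in CWR-R1 than in the libraries labelled WA01 included, among those counted whole, SAP30 (chromosome 4, 173370942 to 173377532), a subunit gene of the SIN3 histone deacetylase complex, at a difference of 3.28 (2.29 to 4.26), and NRARP at 2.36 (1.98 to 2.75). TRIML1 at 3.78 (1.36 to 6.20), SERTAD1 at 3.54 (1.10 to 5.98) and GAB3 at 3.48 (1.62 to 5.34) stood higher still on 1 or 2 IP counts in the library labelled WA01. LAMP5 at 3.14, G6PC2 at 3.07, DLX1 at 2.94 and HOXD4 at 2.93 were also among the 10 highest; the last 3 lie in the lost part of 2q. Among the 5 lowest with at least 50 counts in each pair of libraries were the interferon-induced gene ISG15 (chromosome 1, 1013467 to 1014540) at -3.54 (-4.67 to -2.40), IZUMO4 at -2.95, TWF2 at -2.90 and DRAP1 at -2.85. FGF22 at -2.883 and NEUROG3 at -2.875 had fewer counts in the CWR-R1 pair. With the input of the other line G6PC2, HOXD4 and DRAP1 changed sign, at -0.045, -1.25 and 0.75.

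The difference passed the rule upward in 1686 genes and downward in 1343 of 19261. Upward genes made up 55.7% of these with total-count scaling, 44.6% with TMM factors and 45.1% with median-of-ratios factors, which moved all values by -0.10 and -0.09, so here too the side with more genes turned. The lost part of 2q held 103 of the 1686 upward genes, and chromosomes 7, 8 and 12 held 20.8% of the downward genes. Downward calls rose with gene density, from 4.32% of genes in the sparsest quartile to 11.1% in the densest, while upward calls were 8.68% and 7.68%.

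Pluripotency genes and olfactory receptors lay above the random range in the difference. Pluripotency genes had 8 up and 3 down of 35 (median 0.74, percentile 100; 97.4, within the range, by the mean), with OTX2 at 1.70 and DPPA4 at 1.39 against ZSCAN10 at -2.63. That median followed the inputs, since IP over IP had a pluripotency median of 0.03 (percentile 48.5). With the input of the other line, which adds the same input ratio in place of subtracting it, the list fell to percentile 0.13. Olfactory receptors had 65 up and 26 down of 353 (median 0.46, or 0.43 with zeros at their bound, percentile 100; 77.8 with a count minimum of 100).

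The other 15 lists lay within the range in the difference. Metabolic medians were 0.06 for glycolysis (percentile 49.5, 2 up and 3 down), -0.14 for the TCA cycle (16.0, 5 up and 3 down), -0.11 for oxidative phosphorylation (11.7, 4 up and 8 down), -0.13 for serine and one-carbon genes (12, 1 up) and 0.16 for lipid genes (70.4, 4 down). HOX genes had 4 up and 9 down (median -0.23, percentile 3.04; below the range at 1.98 when matched on gene density). Ribosomal protein genes had 3 up and 11 down of 33 (-0.22, percentile 5.91), and liver and muscle genes 5 up and 1 down of 25 (0.44, percentile 96.5). The medians were 0.10 for neural (percentile 56.2), 0.13 for SOX family (64.5), -0.10 for germ layer (23), -0.04 for prostate (25.3), 0.21 for basal epithelial (71.2), 0.04 for fibroblast (43.6) and 0.01 for cell cycle genes (33.5).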

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

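The tests of explanations in this part, and the setting with the CWR-R1 input for both IPs, were chosen only after the results were seen. Beside 1188 genes higher in both IPs and 261 lower in both, a few genes moved in opposite directions. Genes higher in the CWR-R1 IP and lower in the library labelled WA01 IP numbered 20, and 19 were the reverse. These counts moved with the settings, to 2 and 2 with a minimum of 100 counts, 9 and 12 with 5 counts added, 74 and 63 with a 1.5-fold rule, 7 and 3 with a 3-fold rule, 9 and 19 with the CWR-R1 input for both IPs, and 28 and 56 with the input of the other line. With 1 library per group the difference had no test between replicates, only a counting interval for each gene. Of the 20, 6 were counted whole: C1QB (1.39 in CWR-R1 and -2.21, -5.61 to -0.55, in the library labelled WA01 on 2 counts), CHN1, HOXD12, NDUFAF2, TEX13B and MAGEC3. Of the 19, 10 were counted whole, among them RPS18 (-1.02 and 1.56), the myoglobin gene MB (-1.28 and 1.26) and the DNA polymerase gene POLD1 (-1.02 and 1.44). Against the CWR-R1 input, CHN1 and HOXD12, both in the lost part of 2q, stood at 0.21 and 0.99 in the library labelled WA01 IP.

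The library labelled WA01 IP had coverage steps over the same segments as the CWR-R1 libraries, though smaller over 1q and 11q. A swap of the IPs is argued against by the CWR-R1 IP, which had its own 2q step of -0.80 (-0.91 to -0.71). A candidate explanation is DNA of CWR-R1 or a related line in this library, by a wrong label or a mixed sample, since its 2q step of -0.60 (-0.78 to -0.35) was absent from the WA01 input; against the CWR-R1 input a mixed share of 74.1% (46.8 to 91.6) would give the 2q step, 80.0% (65.8 to 91.7) that of chromosomes 7, 8 and 12, 29.6% (4.7 to 78.3) that of 11q and 26.4% (11.3 to 39.2) that of 1q, and 1q stood apart from chromosomes 7, 8 and 12 also against the CWR-R1 IP, at 40.9% (17.6 to 60.7) and 82.7% (68.0 to 94.8). Binding that differs along the segments cannot be told apart from this, because the step of -0.79 (-0.93 to -0.45) at 93 genes near input in the CWR-R1 IP does not show that these genes were free of SOX2 in the other line. Also open is WA01 culture that had gained these changes, and until this is settled the comparison of lines does not separate prostate cancer cells from stem cells.

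Values beyond 5 on the log2 scale sat almost wholly in genes with shared reads, 27 of 29 in CWR-R1 (93.1%) against 25.4% of all tested genes. The sharing out of reads between near-identical genes is thus a candidate explanation for the size of these values. Enrichment of the named copy itself cannot be told apart from it, because the summed F8A genes, at 3.60 (3.38 to 3.83), lie below their highest member by construction. The summed F8A genes were enriched, 12.1-fold in CWR-R1 and 11.4-fold in the library labelled WA01, and whether SOX2 binds there was not tested.

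Higher calls were more frequent in gene-dense regions, 5.25% of genes in the sparsest quartile and 11.7% in the densest in CWR-R1, and 6.60% and 22.3% in the library labelled WA01 IP. That the trend alone placed the SOX family, neural and HOX lists is argued against by lists matched on gene density, where their lowest percentile over both IPs was 99.99. A sequence composition favoured in the IP libraries and binding near gene-dense promoters cannot be told apart by the correlation of 0.22 with gene density across genes, because no genome sequence was used.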

How the results depend on the processing

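The settings with genes counted whole, the CWR-R1 input for both IPs, 6 chromosomes left out and lists matched on gene density were chosen only after the results were seen. Over all settings, named genes kept their side of the rule in 2739 comparisons, passed it newly in 88, lost it in 190 and changed sign in 19. A sign change was counted only where the gene was called in the main setting or in the alternative. Sign changes of genes called in neither would be among the 2739. Lists kept their place against the random range in 298, moved newly outside it in 26, fell within it in 15 and crossed to its other side in 1. In the order higher and lower, the counts were 1595 and 894 in CWR-R1, 2529 and 2916 for WA01, 1686 and 1343 for the difference, and 1188 and 261 in both, and 2 lists lay outside in the difference. Counts not named below stayed within 1.5 times these. TMM factors gave 1821 lower for WA01 and 136 lower in both, and median-of-ratios factors 571 lower in CWR-R1, 1742 for WA01 and 132 in both. A minimum of 100 counts tested fewer genes and gave 417 lower in CWR-R1, 1627 lower for WA01, 943 and 699 for the difference, 70 lower in both and 4 lists. Adding 5 counts, which shrinks ratios of few counts, gave 532 lower in CWR-R1, 1490 lower for WA01, 722 higher for the difference and 82 lower in both. By construction a 1.5-fold rule gave more, 2801 and 3221 in CWR-R1, 5421 lower for WA01, 3070 and 2721 for the difference, and 2022 and 1434 in both. A 3-fold rule gave fewer, 798 and 224, 1272 and 1116, 649 and 385, and 553 and 51. With the input of the other line 1622 were lower in CWR-R1, 2129 lower for the difference, and 7 lists lay outside. Genes counted whole gave 585 lower in CWR-R1 and 156 lower in both, and 6 chromosomes left out gave 1055 higher in CWR-R1, 1566 higher for WA01, 758 lower for the difference and 775 higher in both, all from fewer genes. Matching on gene density gave 4 lists outside in the difference. Scaling factors move all values of a comparison by a constant, and another input brings the ratio of the inputs into the values that use it. Why the inputs differ, and the cause for the density matching, were not tested.

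Sign changes counted in this way came only with another input. The difference is IP over IP minus the ratio of the inputs, and exchanging the inputs adds that ratio instead. By construction its sign turns where the ratio of the inputs is larger in size than IP over IP. Why the inputs differ was not tested. With the input of the other line the sign changes were, in the difference, G6PC2 -0.045, HOXD4 -1.25, DRAP1 0.75, ZFP42 -0.33, SOX1 -1.34, SIX3 -2.76, FOXA2 -0.98, TRIM29 -0.30, FAP -1.39, IDH3G 0.26, ASNS 1.10, INSIG1 0.24, HOXD12 -2.32, HOXA7 0.46 and SERPINA1 -0.27, and, for WA01 IP over input, HOXD12 0.99. The pluripotency list crossed from above the random range to below it, at percentile 0.13. With the CWR-R1 input for both IPs the sign changes were SOX1 -0.004 and FAP -0.043 in the difference and HOXD12 0.99 for WA01. The median input ratio of genes on chromosomes 7, 8 and 12 over the other autosomes was 0.42, also with TMM factors and with a minimum of 100 counts. A paired fit of IP against input with line as block would leave 1 residual degree of freedom and was not run. Alternatives planned for peaks were not run, since no peak lists were used. Depth limited the library labelled WA01 IP most, where 35 counts was the median of a gene.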

Other observations

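IP over IP, which needs no input, was chosen only after the results were seen, as were its genes and the input extremes. Among genes counted whole, ST7, a candidate tumour suppressor gene, had 629 counts in the CWR-R1 IP and 31 in the library labelled WA01 IP, a log2 ratio of 2.80 (2.28 to 3.31), and its IP over input was 2.34 in CWR-R1. The mitochondrial ribosome gene MRPS15 stood at 2.60 (1.23 to 3.97) and XRCC6, which encodes the DNA end-binding protein Ku70, at 2.55 (1.31 to 3.79). The other way, NEUROG3, a master gene of endocrine pancreas differentiation, stood at -3.88 (-4.88 to -2.87), the angiogenic growth factor gene PGF at -2.80 (-3.44 to -2.16), ISG15 at -2.79 (-3.61 to -1.96), LAGE3 at -2.72 (-3.44 to -2.01) and the monocarboxylate transporter gene SLC16A11 at -2.49 (-2.97 to -2.02). SOX2 stood at 0.46 (0.03 to 0.89).

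In gene lists, IP over IP was low for HOX genes, with 4 intervals above 0 and 20 below of 38 (median -0.40, percentile 0.15), and for germ layer genes, with 0 above and 9 below of 20 (median -0.41, percentile 1.47). It was high for olfactory receptors (median 0.42, percentile 100). Downward calls of the difference were more frequent in gene-dense regions, at 11.1% of genes in the densest quartile and 4.32% in the sparsest. Whether gene density places these lists, or the genes named for IP over IP, was not tested. Prostate genes (median 0.09, percentile 60.9) and pluripotency genes (0.03, percentile 48.5) lay within the random range, unlike in the ratio of the inputs.

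Several of the lowest ratios of CWR-R1 input over WA01 input were in the lost part of 2q. CHRNA1, a muscle acetylcholine receptor gene, stood at -2.46 (-3.05 to -1.88), HOXD12 at -2.42 (-2.98 to -1.85), INHBB at -2.10 (-2.54 to -1.65), HOXD4 at -2.09 (-2.63 to -1.55) and the cortical transcription factor gene TBR1 at -1.73 (-2.16 to -1.29). The forebrain gene SIX3, at -1.86 (-2.26 to -1.45), and FSHR, at -1.61 (-1.89 to -1.33), lie on 2p in a window from 42169338 to 62506469 whose input ratio was also low, at -0.52. Coverage of that window alone was -0.48 in the CWR-R1 input, -0.26 in the CWR-R1 IP, -0.21 in the library labelled WA01 IP and 0.13 in the WA01 input. The cardiac and limb gene HAND2, on chromosome 4, stood at -2.08 (-2.67 to -1.48).

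Over 236 windows the slope of the IP over IP ratio on the input ratio was 0.21 (0.11 to 0.31, jackknife over 23 chromosomes). Simulated libraries gave 1.01 when each IP held DNA of its own line, 0.52 with equal mixing and 0.00 when both held the same DNA. These libraries did not follow the simulated scale closely, since CWR-R1 IP over its own input had a slope of -0.26 (-0.50 to -0.02). The slope of CWR-R1 IP over WA01 input, 0.74 (0.50 to 0.98), is the same result by construction, because that ratio adds the input ratio. The slope of 0.21 is therefore not read as a mixing share.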
